A study of Homo sapiens with 6 samples.

How the data were processed

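The series holds 6 poly(A) RNA sequencing libraries of the human colorectal cancer line SW480. Per the labels, 3 wells received DHA at 20 µg/mL and 3 received 0.1% DMSO, all for 4 h. Poly(A) RNA was isolated with magnetic beads and libraries were made with a NEBNext Ultra II kit, per the labels' protocols. No label says that the wells came from separate cultures or days, so p-values measure only the spread between these wells, which may be technical. Each library was assigned to its group from its treatment label. The titles of the DHA libraries misspell the word treatment, and 1 of them reads DNA in place of DHA, so its treatment label was used.

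The submitters' processing notes name HISAT2 and DESeq2 1.18.1, and per the labels' design text reads were filtered, mapped and compared with DESeq2. The counting tool, its strand setting, the annotation and the genome build are not given in the sources used here. Of the gene identifiers in the deposited count table, 40715 were found in GENCODE release 29 (GRCh38), and 97.0% of those had the same coordinates and strand, so coordinates are given as in the deposited table and gene types are taken from that release.

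The authors deposited raw read counts for 40846 genes. Among these, 1696 genes share 143 names, and all genes of a shared name carry identical counts, so that one row per name was kept, which left 39293. These are names such as U1 and Y_RNA, and their counts may be sums over a family, which was not tested. For 12 genes the deposited name had turned into a date; they were tested but not named. Left out were 32 lines of annotation text with no gene. A further deposited table is named as FPKM, yet its values are CPM: each equals the count divided by the library total and multiplied by 1e+06, to a relative difference of 9.99e-15, and over one row per name each library sums to between 999997 and 999999. It was therefore treated as CPM, not FPKM as planned. The authors' deposited comparison table gives log2 fold changes, p-values and adjusted p-values from their own test, and only genes past its limits.

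Counts were analysed in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and tables and figures were handled in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. Genes were kept by filterByExpr, libraries were scaled by TMM, and DHA was compared with control by the quasi-likelihood test (glmQLFit and glmQLFTest) with Benjamini-Hochberg adjustment over 15811 genes. A gene passed at an adjusted p under 0.05, and the second count added an absolute log2 fold change of at least 1. Standard errors of log2 fold changes were taken from the F statistic. CPM values use library totals. The common biological coefficient of variation was 0.0902, and 10052 genes had an unadjusted p under 0.05. The smallest p of an exact permutation of 3 against 3 is 0.1, so single values between groups were described and not tested.

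The 34 gene lists were fixed before the data were examined. Of these, 31 had at least 3 tested members. They were tested with camera, 2-sided, with a preset correlation of 0.01 and Benjamini-Hochberg adjustment over the lists. Camera with an estimated correlation and fry were alternatives. The former has only the few residual degrees of freedom of 6 libraries, so its p can rise without correlated members. Named genes followed a rule fixed at the same time: the 12 largest rises and 12 largest falls among genes past the adjusted p, with a mean of at least 5 CPM, a gene symbol and no overlap between the groups; for each list up to 4 members with the smallest adjusted p and the members needed to give the direction of the others, read as those that passed in the less frequent direction where 3 or fewer did, a limit set after the values were seen; and the highest markers of other cell types. Some genes that the rule names are not reported here.

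Library totals ran from 14291726 to 18938456 counts, at which 3 counts correspond to between 0.158 and 0.210 CPM per library. Pairs of libraries of the same group differed by more than sampling noise, with a chi-square per gene from 1.70 for the DHA libraries of replicates 1 and 3 to 16.1 for those of replicates 2 and 3, and from 117 to 152 between groups, so no library was taken for a copy. The fit was tested on simulated data drawn for 15717 genes from the real means and library sizes of this comparison: 99 of 100 genes changed by a log2 of 1 and 100 of 100 changed by 2 were recovered, 7 calls, or 3.11%, were false, the shifted list was called, and 0 of 30 unchanged lists were. Genes were simulated independently, with a common dispersion, no trend with GC content and few changed genes. The simulation therefore does not test the scaling where 9431 of 15811 genes passed, nor list calls where members vary together.

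Alternatives fixed in advance were other size factors, library totals alone, DESeq2, no low-count filter, a filter at 1 CPM in 3 libraries, limma on log2(CPM + 1) for genes with a mean of at least 0.5, a block on the replicate number, and leaving out each library. Added after seeing the data were all rows as deposited, an offset that removes the trend of each library with GC content and exon length, and leaving out mitochondrial genes. KEGG pathway names in the deposited tables were used for 291 pathways of 15 to 300 genes, chosen after seeing the data.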

Results

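RNA was profiled in SW480, an epithelial cell line established from a human colorectal cancer. Cells in 3 wells received dihydroartemisinin (DHA), the active metabolite of the artemisinin antimalarials and a compound under study as an anticancer agent, at 20 µg/mL for 4 h. Cells in 3 control wells received 0.1% DMSO for the same time. The labels do not give the DMSO content of the DHA wells. Poly(A)-selected RNA was sequenced, and the deposited values are read counts per gene. The control libraries held 18938456, 15807037 and 16681847 counts, and the DHA libraries held 14810697, 16653074 and 14291726. The comparison asks which transcripts differed after 4 h of the compound in these colorectal cancer cells.

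After 4 h of DHA, SW480 cells held far more transcript of the immediate early transcription factors, which cells induce without new protein synthesis. FOS rose from 9.81 ± 2.87 to 1465 ± 125 CPM and JUN from 41.6 ± 7.78 to 2459 ± 158 CPM (mean ± SD, n = 3 per group). Higher in DHA were also 14 of 15 heat shock genes, 14 of 24 integrated stress response genes, 10 of 14 antioxidant genes and 13 of 13 replication-dependent histone genes. With an estimated correlation between genes, the list test held for the histones and not for the other lists, at adjusted p of 0.217, 0.344 and 0.141. Lower were 17 of 22 mitotic genes, 8 of 11 fatty acid synthesis genes and 11 of 14 Wnt targets, lists that did not hold with an estimated correlation, at adjusted p of 0.380, 0.380 and 0.217. SOX4, a transcription factor downstream of Wnt signalling, fell from 190 ± 11.8 to 55.0 ± 4.79 CPM. Of 15811 genes tested, 9431 passed an adjusted p of 0.05 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 4674 of them higher and 4757 lower in DHA. This balance moved with the scaling, to 3854 higher and 5601 lower with library totals alone in place of TMM. A change of at least 2-fold was added for 2480 of these, 1695 higher and 785 lower, and 865 of the 1695 had a control mean under 1 CPM.

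**Figure D1:**
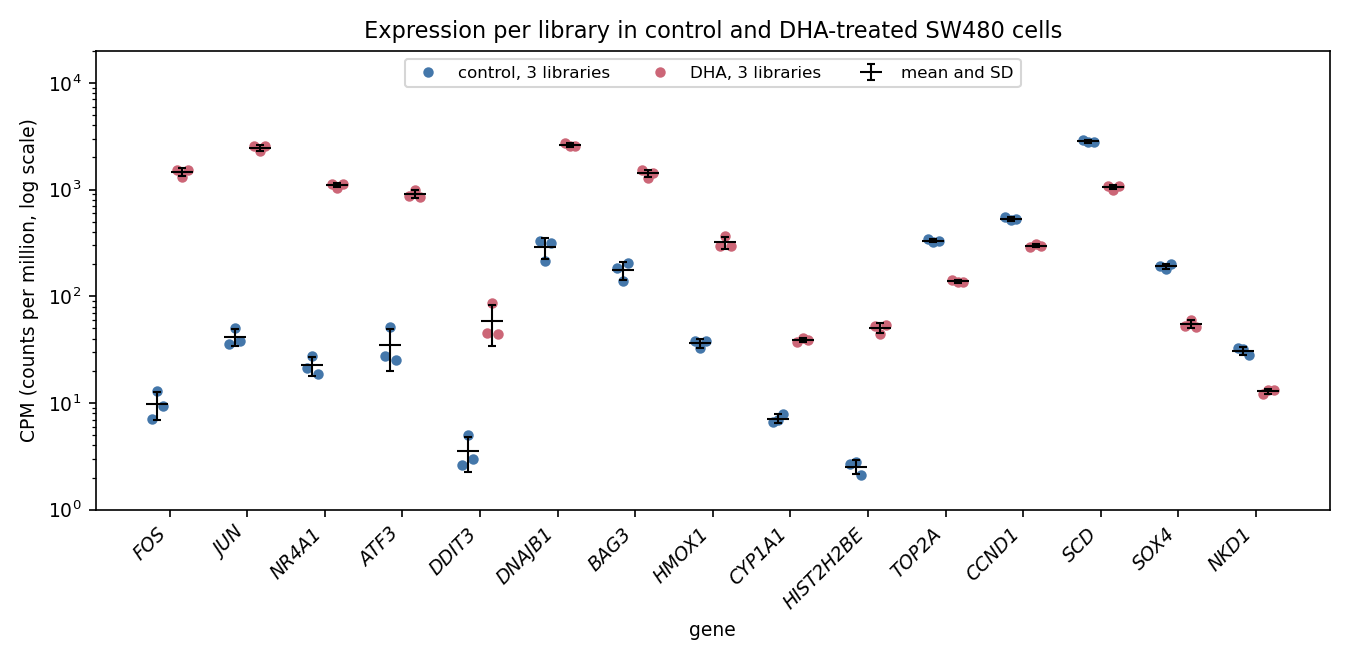
CPM on a log scale for 15 genes in the 3 control and 3 DHA libraries; points are libraries, and black marks give the mean and SD of each group. FOS, JUN and NR4A1 rose by log2 fold changes of 7.33, 5.98 and 5.71, whereas TOP2A, CCND1, SCD, SOX4 and NKD1 fell by 1.17, 0.74, 1.33, 1.70 and 1.17 on the log2 scale.

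The largest rises were led by immediate early genes. FOS (chromosome 14, 75278774 to 75282230) had a log2 fold change of 7.33 ± 0.18 (SE), FOSB of 7.25 ± 0.18 and the zinc finger factor EGR2 of 7.12 ± 0.29, or 7.90 without the control library of replicate 2. The orphan nuclear receptors NR4A3 and NR4A1 rose by 6.42 ± 0.17 and 5.71 ± 0.14, EGR3 by 6.02 ± 0.24, and JUN (chromosome 1, 58780788 to 58784327) by 5.98 ± 0.14. CTGF and CYR61, secreted matricellular proteins, rose by 6.14 ± 0.17 and 5.54 ± 0.13. The other members of the top 12 were RASD1, a Ras-related GTPase, at 6.21 ± 0.30, ARL14 at 6.15 ± 0.27 and AC105339.2 at 6.77 ± 0.29. With few control counts, ARL14 was at 6.77 without the control library of replicate 1 and AC105339.2 at 7.47 without that of replicate 2, and RASD1 was at 5.58 with a GC and length offset. AC105339.2 is annotated as antisense, and its reads cannot be separated from those of the opposite strand because the strand setting of the counting is not given in the sources used here. In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, the adjusted p of these 12 genes lay between 1.21e-10 for JUN, NR4A1 and CYR61 and 2.16e-08 for RASD1. All 20 tested members of the immediate early list rose, with a median log2 fold change of 4.51 and the phosphatase DUSP1 at 4.22 ± 0.10 among them. The list test (camera) gave an adjusted p of 6.11e-86, and an adjusted p of 0.0207 with an estimated correlation.

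Most heat shock genes rose, as did part of the integrated stress response. Of 15 heat shock genes, 14 rose and 1 did not pass, with a median of 1.39. HSPA1A, an inducible Hsp70, rose by 4.09 ± 0.17, its co-chaperone DNAJB1 from 287 ± 62.3 to 2612 ± 95.3 CPM (SD, n = 3), the Hsp70 nucleotide exchange factor BAG3 by 3.10 ± 0.14 and HSPH1 by 2.01 ± 0.11. HSPA1A shares most of its sequence with a neighbouring copy, so the division of reads between both is uncertain. The list test gave an adjusted p of 2.25e-11, and an adjusted p of 0.217 with an estimated correlation. In the integrated stress response list, 14 of 24 genes rose, 10 did not pass and the median was 0.87. PPP1R15A, a regulatory subunit of the eIF2alpha phosphatase, rose by 3.46 ± 0.10, the transcription factors ATF3 and DDIT3 by 4.80 ± 0.23 and 4.16 ± 0.29, and SESN2 by 2.38 ± 0.19. Its adjusted p was 1.32e-06, and the adjusted p was 0.344 with an estimated correlation. Genes of endoplasmic reticulum folding and degradation moved both ways, with 8 of 18 higher, 6 lower and an adjusted list p of 0.689. HERPUD1 rose by 2.07 ± 0.11 and DNAJB9 by 1.04 ± 0.09, while the degradation adaptor SEL1L fell from 87.0 ± 0.963 to 35.9 ± 2.11 CPM and DNAJC3 fell by 0.73 ± 0.08 on the log2 scale. The counts adjusted over the list alone were 14, 14 and 8 higher and 0, 0 and 7 lower for the heat shock, integrated stress response and endoplasmic reticulum lists.

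Among 14 NRF2 antioxidant genes, 10 rose, 2 fell and 2 did not pass. HMOX1, which encodes the heme-degrading enzyme heme oxygenase 1, rose from 36.2 ± 3.19 to 320 ± 42.5 CPM (SD, n = 3). OSGIN1 rose by 2.94 ± 0.15, and GCLC and GCLM, the subunits of the enzyme that begins glutathione synthesis, by 0.53 ± 0.07 and 1.06 ± 0.15. PGD fell by 0.29 ± 0.07 and ME1 fell by 0.20 ± 0.07 on the log2 scale, the latter a call lost in 4 of 16 alternative settings. The antioxidant list had an adjusted p of 0.000716, and the adjusted p was 0.141 with an estimated correlation. In the iron and heme list, 5 of 18 genes rose and 9 fell, with an adjusted list p of 0.638. Beside HMOX1, the ferric reductase CYBRD1 fell by 1.17 ± 0.10, the heme synthesis enzyme CPOX fell by 0.86 ± 0.07 and the iron importer SLC11A2 fell by 0.86 ± 0.08. Of 17 ferroptosis regulators, 7 rose and 6 fell, with an adjusted list p of 0.641. The small heat shock protein HSPB1 rose by 1.39 ± 0.10, or 0.72 with a GC and length offset, and the prostaglandin synthase PTGS2 by 3.23 ± 0.26, while ACSL4, which activates long-chain polyunsaturated fatty acids, fell by 0.76 ± 0.07 and the transferrin receptor TFRC fell by 0.65 ± 0.07. Of 5 metallothionein and metal response genes, 4 rose, with MT2A at 0.94 ± 0.08, the zinc exporter SLC30A1 at 0.83 ± 0.08 and MT1E at 0.83 ± 0.09. The adjusted p of this list was 0.0195, and the adjusted p was 0.216 with an estimated correlation. The fourth member, MTF1, had a log2 fold change of 0.23 ± 0.09 whose call was lost in 10 of 16 alternative settings. Of 7 xenobiotic response genes, 5 rose, among them the aryl hydrocarbon receptor targets CYP1A1 at 2.55 ± 0.10, CYP1B1 at 2.89 ± 0.14, TIPARP at 1.87 ± 0.09 and AHRR at 1.41 ± 0.09. Its adjusted p was 1.32e-06, and the adjusted p was 0.122 with an estimated correlation. All 5 metallothionein and metal response genes passed when adjusted over the list alone, and the counts of the other 4 lists stayed as given.

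Inflammatory and mesenchymal genes rose as well, several of them from very low levels. Of 13 NF-kB and inflammatory genes, 11 rose and 1 fell, with a median of 1.42. TNF had 0 counts in the 3 control libraries and 6.06 ± 0.282 CPM in DHA (SD, n = 3), at least 103.9-fold higher when set against a floor of 3 counts over the control group. RELB rose by 2.10 ± 0.12, the chemokine CXCL8 by 3.78 ± 0.23 and NFKB2 by 1.21 ± 0.08. NFKB1 fell by 0.19 ± 0.07, a call lost in 6 of 16 alternative settings. Tested as a list, they had an adjusted p of 1.32e-06, and the adjusted p was 0.164 with an estimated correlation. Of 8 epithelial-mesenchymal transition genes, 6 rose and 1 fell, with the repressor SNAI1 from 25.6 ± 1.80 to 206 ± 28.3 CPM, and SNAI2 and TGFBI at 3.54 ± 0.30 and 4.06 ± 0.52 from control means under 1 CPM. E-cadherin (CDH1) fell by 0.28 ± 0.07 on the log2 scale, a call that ended with a GC and length offset. The list's adjusted p was 6.49e-06, and the adjusted p was 0.0930 with an estimated correlation. Of 14 interferon genes, 2 rose and 6 fell, with an adjusted list p of 0.638. ISG15 and IRF7 rose by 2.07 ± 0.16 and 1.45 ± 0.14, or 1.26 and 0.77 with that offset, while OAS3 fell by 1.08 ± 0.07. With counts adjusted over the list alone, 2 NF-kB genes were lower in place of 1, and the counts of the other lists here stayed as given.

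Genes linked to p53, apoptosis and hypoxia changed in both directions. Of 18 p53 targets, 10 rose and 3 fell. PLK3 rose by 2.33 ± 0.08, the cell cycle inhibitor CDKN1A by 1.39 ± 0.07, GADD45A by 2.24 ± 0.12 and BTG2 by 1.74 ± 0.09, whereas ZMAT3 fell by 1.36 ± 0.10, RRM2B fell by 0.74 ± 0.07 and SPATA18 fell by 0.96 ± 0.27. The p53 list had an adjusted p of 0.00204, and the adjusted p was 0.141 with an estimated correlation. Of 20 apoptosis regulators, 10 rose and 7 fell, with an adjusted list p of 0.0677. The BH3-only genes PMAIP1 and BCL2L11 rose by 1.55 ± 0.13 and 0.82 ± 0.08, the anti-apoptotic MCL1 by 1.43 ± 0.07, and the caspase inhibitor XIAP fell by 1.07 ± 0.09. Of 22 hypoxia and glycolysis genes, 10 rose and 7 fell, led by the vasodilator peptide gene ADM at 4.12 ± 0.11, ANKRD37 at 1.73 ± 0.19, PFKFB3 at 0.90 ± 0.08 and NDRG1 at 0.62 ± 0.07. The list's adjusted p was 0.0288, and the adjusted p was 0.255 with an estimated correlation. Of 20 autophagy and lysosome genes, 10 rose and 3 fell. MAP1LC3B rose by 1.43 ± 0.09, the transcription factor TFE3 by 1.38 ± 0.09 and the cargo receptor SQSTM1 by 0.98 ± 0.08, while LAMP2 fell by 0.81 ± 0.07 and BECN1 fell by 0.32 ± 0.08, a call that ended with a GC and length offset. The adjusted list p was 0.0540. It passed with other size factors at 0.0485, with the replicate block at 0.0383 and with the offset at 0.0219. Without the control library of replicate 2 it passed at 0.0361, and without the DHA libraries of replicates 1 and 3 at 0.0424 and 0.0411. The adjusted p was 0.00481 with fry, which tests a list against no change, and 0.502 with an estimated correlation. Adjusted over the list alone, 4 autophagy and lysosome genes were lower in place of 3, and the other counts stayed as given.

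Mitotic transcripts fell. Of 22 G2/M genes, 17 fell and 5 did not pass, with a median of -0.65. DNA topoisomerase TOP2A fell from 331 ± 11.1 to 138 ± 3.27 CPM (SD, n = 3), the kinetochore gene CENPF fell by 1.04 ± 0.08, and BUB1B and KIF20A each fell by 0.97 ± 0.09. The G2/M list had an adjusted p of 3.02e-06, and the adjusted p was 0.380 with an estimated correlation. Of 22 G1/S and replication genes, 13 fell and 2 rose, with cyclin D1 (CCND1) at -0.74 ± 0.07, the checkpoint adaptor CLSPN at -1.15 ± 0.12, the helicase subunit MCM4 at -0.84 ± 0.09 and UHRF1 at -0.81 ± 0.09. The 2 higher ones, CDT1 at 0.35 ± 0.10 and CDC45 at 0.21 ± 0.08, lost their calls in 4 and 11 of 16 alternative settings, and with a GC and length offset 0 members rose and 14 fell. This list had an adjusted p of 0.0228, and an adjusted p of 0.561 with an estimated correlation. Of 17 DNA damage repair genes, 8 fell and 1 rose, with an adjusted list p of 0.0970. The mismatch repair gene MSH6 fell by 0.62 ± 0.10, PARP1 fell by 0.71 ± 0.07 and FANCI fell by 0.33 ± 0.06, a call that ended with a GC and length offset. The higher one was XRCC1 at 0.28 ± 0.10, which lost its call in 8 of 16 alternative settings and turned to -0.016 ± 0.09 with that offset, under which 5 members rose and 3 fell. Of 14 Wnt targets, 11 fell and 1 rose. SOX4 fell by 1.70 ± 0.08, the feedback inhibitors NKD1 and RNF43 fell by 1.17 ± 0.10 and 0.67 ± 0.07, and the higher gene was the intestinal stem cell receptor LGR5, from 0.0844 ± 0.146 to 2.48 ± 0.179 CPM, with 4 counts in the control library of replicate 2 and 0 in the other controls. The list's median was -0.46 and its adjusted p 0.00428, and the adjusted p was 0.217 with an estimated correlation. Adjusted over the list alone, 3 G1/S genes were higher in place of 2, and the other counts stayed as given.

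Most fatty acid synthesis genes fell. Of 11 fatty acid synthesis genes, 8 fell and 2 rose. The desaturase SCD fell from 2825 ± 66.5 to 1051 ± 44.6 CPM (SD, n = 3), the elongase ELOVL6 fell by 0.97 ± 0.08, FADS1 fell by 0.75 ± 0.07 and ACLY fell by 0.70 ± 0.07. ACSS2 and SREBF1 rose by 0.43 ± 0.08 and 0.31 ± 0.07, and the call of SREBF1 ended with a GC and length offset. The list's adjusted p was 0.0146, and the adjusted p was 0.380 with an estimated correlation. Of 20 cholesterol synthesis genes, 11 fell and 3 rose, with an adjusted list p of 0.147, or 0.0453 without the control library of replicate 2. LSS and MSMO1 fell by 0.80 ± 0.08 and 0.69 ± 0.09, while IDI1 rose by 0.48 ± 0.09 and MVD by 0.46 ± 0.08. The call of MVD ended with the same offset. Of 15 PPAR and fatty acid oxidation genes, 4 rose and 7 fell, with an adjusted list p of 0.827. ANGPTL4 rose by 3.40 ± 0.11 and ACADVL by 0.75 ± 0.08, while the mitochondrial fatty acid importer CPT1A fell by 0.80 ± 0.07 and PPARA fell by 1.02 ± 0.10. Of 16 one-carbon and amino acid transport genes, 5 fell and 1 rose, with an adjusted list p of 0.349. SLC38A1 fell by 0.86 ± 0.09, ALDH18A1 fell by 0.63 ± 0.07, SHMT1 fell by 0.42 ± 0.08 and SLC7A1 fell by 0.46 ± 0.11, and SLC1A5 rose by 0.41 ± 0.10, a call that ended with a GC and length offset. Among cholesterol synthesis genes 12 were lower, in place of 11, when adjusted over the list alone, and the other counts of these lists stayed as given.

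Cytosolic ribosomal protein transcripts rose by small amounts. Of 32 tested, 25 rose, 1 fell and 6 did not pass, with a median of 0.54. RPL11 rose by 0.68 ± 0.07, RPL18 by 0.73 ± 0.07 and RPL32 by 0.54 ± 0.07, and the lower gene was RPS23 at -0.30 ± 0.09, whose call was lost without the DHA library of replicate 3 and with a GC and length offset. These genes have many processed pseudogenes, so reads may be divided among copies. The ribosomal protein list had an adjusted p of 0.000169, and the adjusted p was 0.546 with an estimated correlation. Of 21 ribosome biogenesis genes, 6 rose and 9 fell, with an adjusted list p of 0.717. The box C/D snoRNP components NOP56 and NOP58 rose by 0.77 ± 0.07 and 0.82 ± 0.08 and RRP12 by 0.67 ± 0.06, while WDR12 fell by 0.70 ± 0.07. Of 24 nuclear-encoded respiratory chain genes, 9 rose and 4 fell, with an adjusted list p of 0.717. SDHC and NDUFS1 fell by 0.75 ± 0.06 and 0.59 ± 0.07, NDUFV1 rose by 0.55 ± 0.10 and CYC1 by 0.39 ± 0.07, which turned to -0.21 ± 0.08 with a GC and length offset. With that offset 3 respiratory chain genes rose and 4 fell, and 3 ribosome biogenesis genes rose and 10 fell. Adjusted over the list alone, 26 ribosomal protein genes, 7 ribosome biogenesis genes and 6 respiratory chain genes were higher, and the lower counts stayed as given.

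**Figure D2:**
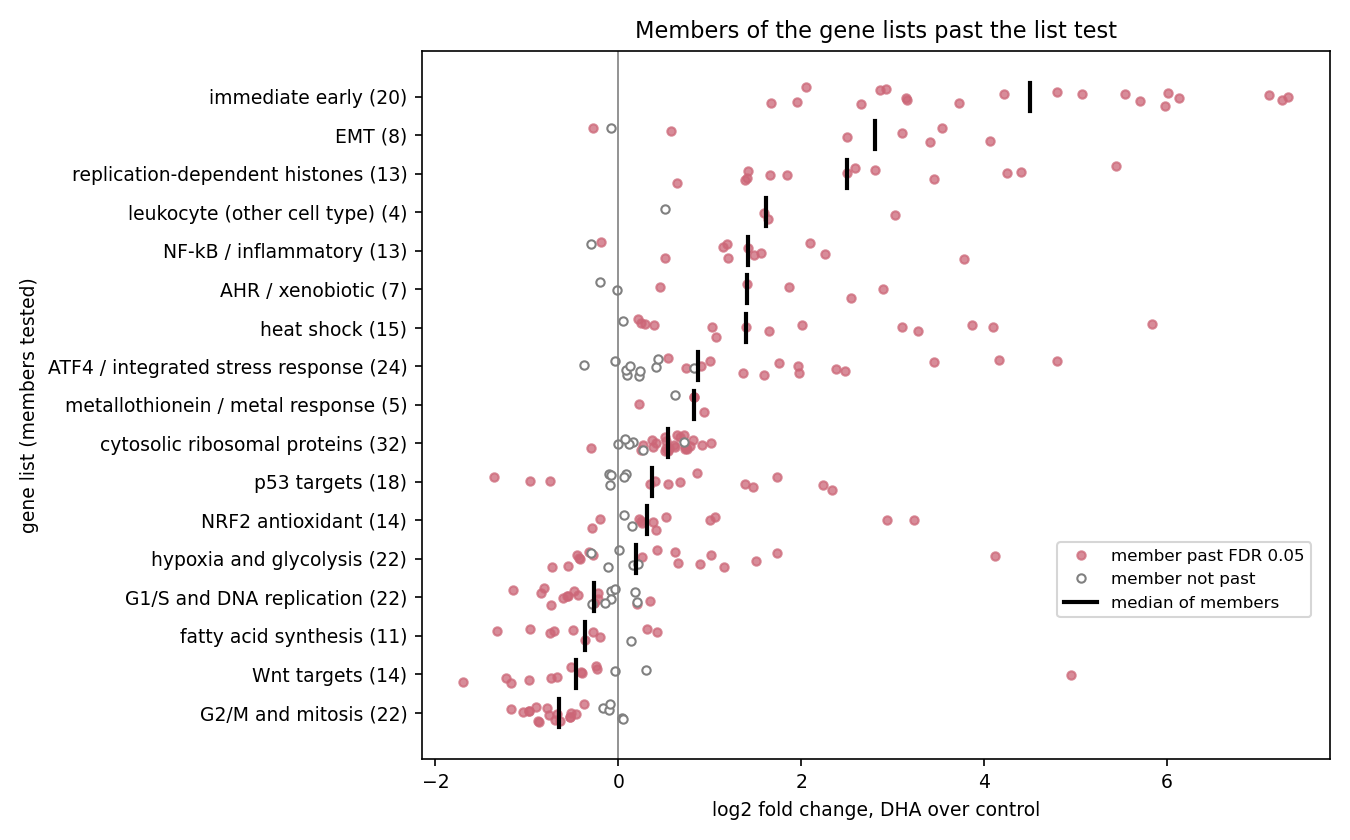
Log2 fold changes, DHA over control, of the members of the 17 gene lists past an adjusted p of 0.05 in the list test with a preset correlation; filled points passed the gene test, open points did not, and black bars are medians over all tested members. Of these lists, only the immediate early and histone lists held with an estimated correlation. TNF, with 0 counts in controls, is left out of the points. Medians ran from -0.65 for the G2/M list to 4.51 for the immediate early list.

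Mitochondrial transcripts took a larger share of the DHA libraries. All mitochondrial genes held 8.61 ± 0.732% of counts in control and 12.7 ± 0.948% in DHA (SD, n = 3), and the mitochondrial ribosomal RNAs rose from 1.30 ± 0.0764% to 3.50 ± 0.353%. Of 13 mitochondrial-encoded protein genes, 9 rose and 3 fell, with an adjusted list p of 0.278. MT-CO3 and MT-CO2 rose by 0.55 ± 0.09 and 0.53 ± 0.10, calls that ended with a GC and length offset, while MT-ND6, the gene on the light strand, fell by 1.22 ± 0.13, MT-ND5 fell by 0.68 ± 0.10 and MT-ND1 fell by 0.23 ± 0.09, a call lost in 6 of 15 alternative settings. With the offset 3 of the 13 rose and 3 fell. Adjusted over the list alone, these counts stayed as given. All 13 tested replication-dependent histone genes rose, also adjusted over the list alone, with a median of 2.50 and HIST2H2BE at 4.41 ± 0.14, HIST1H4H at 4.25 ± 0.31, HIST1H2AG at 2.59 ± 0.16 and HIST1H1C at 1.42 ± 0.10. Most such transcripts end without a poly(A) tail, and near-identical copies can share reads. This list had an adjusted p of 7.24e-12, and an adjusted p of 0.0242 with an estimated correlation. Genes with at least 1 count numbered 24388 ± 49.1 in control and 26346 ± 636 in DHA (SD, n = 3), although the DHA libraries held fewer counts on average.

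**Figure D3:**
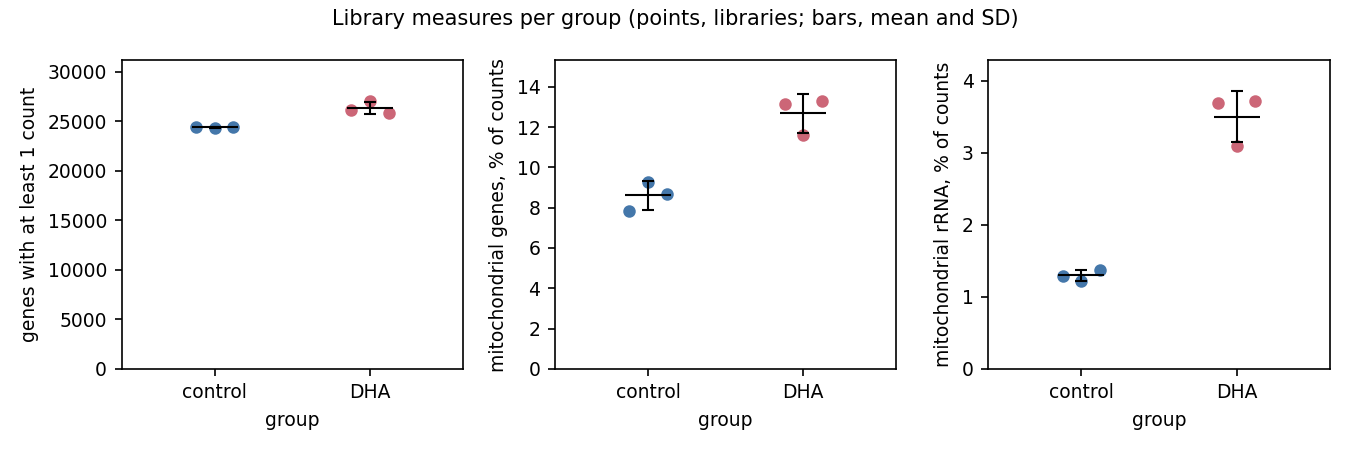
Genes with at least 1 count, and the percentages of counts in all mitochondrial genes and in mitochondrial ribosomal RNAs, per library in the control and DHA groups; points are libraries, and bars give the mean and SD of 3. Each DHA library lay above each control library in all 3 measures, a separation that chance gives in 10% of splits of 3 against 3.

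Markers of the line and of other cell types were read beside these changes. Of 7 colon epithelial identity genes, 4 rose and 3 did not pass, with an adjusted list p of 0.196. KRT18 rose by 0.89 ± 0.08, KRT19 by 0.56 ± 0.08 and KRT8 from 2831 ± 189 to 3308 ± 25.9 CPM (SD, n = 3). CA2 rose by 0.31 ± 0.09, lost in 3 of 16 alternative settings, and the calls of CA2 and KRT19 ended with a GC and length offset, which left 2 of the 7 higher. Of 4 leukocyte markers tested, 3 rose, all at low levels. LCP1 went from 2.14 ± 0.100 to 6.05 ± 0.535 CPM, CD14 from 0.527 ± 0.280 to 4.21 ± 1.10 CPM and CSF1R from 0.663 ± 0.153 to 1.93 ± 0.341 CPM, while CORO1A had a log2 fold change of 0.51 ± 0.21 that did not pass here and passed in 5 of 16 alternative settings. The list's adjusted p was 0.0398, and the adjusted p was 0.227 with an estimated correlation. It was also lost without the control library of replicate 2, at 0.0610, and without the DHA library of replicate 2, at 0.0701. The only fibroblast marker tested, COL1A1, rose from 25.1 ± 4.38 to 78.8 ± 12.2 CPM. The endothelial markers ESAM and VWF had log2 fold changes of 0.32 ± 0.12 and 0.21 ± 0.42, of which ESAM passed here and lost its call in 9 of 16 alternative settings. The hepatocyte marker SERPINA1 had -0.10 ± 0.32 and did not pass. Adjusted over the list alone, all 4 leukocyte markers were higher.

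The largest falls were smaller than the largest rises. The 12 largest falls began with RIMS3, a presynaptic scaffold gene (chromosome 1, 40620679 to 40665657), which went from 19.6 ± 1.72 to 4.02 ± 1.16 CPM (SD, n = 3). CCDC65 fell by 1.93 ± 0.16, the homeobox gene HOXA13 fell by 1.89 ± 0.15, the cationic amino acid transporter SLC7A2 fell by 1.89 ± 0.12 and AMER1, a negative regulator of Wnt signalling, fell by 1.88 ± 0.11. CD37 fell by 1.86 ± 0.12, TMEM19 fell by 1.80 ± 0.15, the potassium channel gene KCNC4 fell by 1.79 ± 0.10 and SFT2D2 fell by 1.78 ± 0.08. The remaining 3 have no annotated protein product, MIR4697HG at -1.90 ± 0.16, AC004656.1 at -1.86 ± 0.14 and AC012513.3 at -1.83 ± 0.20. AC004656.1 is annotated as overlapping another gene on its strand, so the division of reads between both is uncertain. Their adjusted p in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment lay between 9.43e-09 for SFT2D2 and 9.50e-06 for AC012513.3. For all 24 genes with the largest rises and falls, the 3 libraries of one group lay above the 3 of the other, as the rule for naming them required.

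The groups separated along the leading principal component, which held 84.1% of the variance, and the next, with 6.51%, set the DHA library of replicate 2 apart from the other DHA libraries. Without that library 9399 genes passed, and 2443 of them changed at least 2-fold. On log2(CPM + 1) of the deposited CPM without TMM scaling, 56.9% of the genes past both limits were higher in DHA, against 68.3% from the counts, and 14 named genes, most of them with low control levels, moved by over 1.5 times, such as AC105339.2 to 3.42. An offset for GC content and length was chosen after the data were seen. With it, 6783 of the 9431 calls kept their direction, 2546 were lost and 102 turned. Of the 2480 at 2-fold, 2302 still passed an adjusted p of 0.05 in the same direction, whatever their size. With the offset 2100 genes passed both limits. Only the immediate early and histone lists held with an estimated correlation, of the 17 that passed among 31 tested. Such a loss need not reflect correlated members. With an estimated correlation, camera also draws its p from the few residual degrees of freedom of 6 libraries in 2 groups. For the p53 and metallothionein lists the estimate was 0.0056 and -0.0195, below the preset 0.01. Their unadjusted camera p still rose from 0.000725 to 0.0250 and from 0.00881 to 0.0557. The histone list, at an estimate of -0.0424, held.

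The authors' deposited table of this comparison, made with a log2 fold change limit of 1 and an adjusted p limit of 0.05, lists 2969 entries, 2188 higher and 781 lower in DHA. They stand for 2938 gene names, and 2183 of these, or 74.3%, were also among the 2480 genes called here at 2-fold. The filter on low counts removed 729 of the names before testing, with a median of 4 counts per library against 61.7 for those kept. All 2209 names present in both had the same sign, and their log2 fold changes correlated with a Spearman rho of 0.9999 across genes, which are not independent replicates. Both sets of fold changes come from the same counts, for names past the authors' limits, so this closeness was largely given in advance. In the authors' deposited table FOS has a log2 fold change of 7.31 and SOX4 of -1.71. DESeq2 run on the same counts without that filter called 2972 genes, of which 2937 were in the authors' deposited table.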

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

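The GC and length offset, the deposited rows without merging and the fit without mitochondrial genes were chosen after seeing the data. Over all alternatives, 8351 to 10983 genes passed, and 1427 to 4077 changed at least 2-fold. Of 2824 comparisons of 177 named genes with their main value, 2732 kept direction and call, 80 lost the call, 5 gained it and 7 turned; of 402 such comparisons of lists, 363 kept both, 17 lost the call, 14 gained it and 8 turned. Without a low-count filter 33752 genes were tested and 4077 changed at least 2-fold, 2872 higher and 1205 lower. The cause of this larger number was not tested. With limma on log2(CPM + 1) there were 1427, 812 of them higher, and 1328 of the genes in the authors' deposited table; this setting also changes the scaling, test and filter, and the cause was not tested. Of 31 lists tested, 17 passed with the preset correlation, 2 with an estimated one and 24 with fry, which tests a list against no change and not against other genes. Past with fry and not with the preset correlation were autophagy and lysosome, apoptosis, ferroptosis and DNA damage repair. The same held for cholesterol synthesis, mitochondrial-encoded and colon epithelial identity genes. Their adjusted p with fry ran from 0.00304 to 0.0447.

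Leaving out 1 library at a time gave 8351 to 9399 genes, 2443 to 2769 at 2-fold and 16 to 18 lists. SERPINA1 then ran from -0.31 to 0.20 and VWF from -0.11 to 0.73. The list test changed direction while medians ran from 0.11 to 0.32 for the respiratory chain, -0.19 to -0.14 for PPAR and -0.20 to -0.050 for ribosome biogenesis; none of these passed. With the GC and length offset CYC1 turned to -0.21, CDT1 to -0.20 and XRCC1 to -0.016. The list test of DNA repair, PPAR, the respiratory chain and mitochondrial-encoded genes changed direction, at medians of -0.028, -0.12, -0.047 and 0.25, none past the threshold. The cause of these turns was not tested. Calls lost in several settings included those of MTF1, CDC45, ESAM, XRCC1, NFKB1, MT-ND1, ME1, CA2, CDT1 and RPS23.

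With the replicate number as a block 8907 genes passed. Libraries of the same number did not deviate together, with correlations of 0.02, -0.11 and -0.07, and not every library correlated best with its own number. Deviations were taken within groups of 3 libraries, so these few values cannot exclude a shared day or batch. Depth limits mainly low genes: in 865 of the 1695 2-fold rises the control mean was under 1 CPM.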

Other observations

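Several changes lay outside the lists fixed in advance, and the genes, classes and pathways in this paragraph were chosen after their values were seen. By adjusted p in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, the leading genes were GADD45B, a stress-induced growth arrest gene, at a log2 fold change of 5.19 ± 0.09 (adjusted p of 8.60e-12) and THBS1, which encodes the matrix protein thrombospondin 1, at 4.73 ± 0.08 (8.60e-12), each higher in 3 of 3 DHA libraries. ARC, an activity-regulated immediate early gene of neurons, rose from 19.4 ± 2.29 to 444 ± 10.3 CPM (SD, n = 3), a log2 fold change of 4.61, or 4.00 with a GC and length offset. The nuclear noncoding RNAs MALAT1 and NEAT1 rose by 1.49 ± 0.08 and 1.20 ± 0.12. Of 610 tested long intergenic noncoding RNAs 224 rose and 88 fell, and of 86 sense intronic RNAs 10 rose and 35 fell, with a median of -0.63. The mitochondrial ribosomal RNAs MT-RNR2 and MT-RNR1 rose by 1.59 ± 0.11 and 1.33 ± 0.12.

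Of 291 KEGG pathways, 9 passed with a preset correlation in camera and 0 with an estimated one, where the smallest adjusted p was 0.653. With an estimated correlation camera has little power at 6 libraries, so the 0 does not speak against the pathways. Even the immediate early list, with 20 of 20 genes higher, reached only an unadjusted camera p of 0.000667 that way. The leading pathway, named for systemic lupus erythematosus and made up largely of histone genes, held 64 tested genes, of which 46 rose and 5 fell (adjusted p of 1.08e-10). The ribosome pathway had 70 of 128 genes higher and 14 lower (0.0185), and oocyte meiosis, which holds many mitotic regulators, had 14 of 97 higher and 51 lower (0.0288).

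Of the tests that follow, the one on poly(A) selection, those on the size of the trends within groups, the values of olfactory receptor genes under 1 CPM and the counts of calls kept under the offset were chosen after the result was seen, and the test of the offset, written for the trend with GC content and length, was assigned to the number of calls after its value was seen. Over 10596 protein-coding genes with a mean of at least 5 CPM, the log2 fold change correlated across genes, which are not independent, with GC content at a Spearman rho of 0.44 and with exon length at -0.32; the median was -0.37 in the fifth of genes with the lowest GC content and 0.33 in the highest. The offset moved the log2 fold changes of these genes by a median of 0.22. Of the 2480 2-fold calls, 2302 still passed an adjusted p of 0.05 in the same direction, though not all at 2-fold. Calls picked for size can hardly be lost to so small a shift, so this count alone does not decide on a bias between libraries. The values argue only against the fitted trend as the whole source of the 2-fold calls. The main calls split into 6783 kept (71.9%), 2546 lost and 102 opposite, and for the lost and opposite ones such a bias stays open. The number of genes past the threshold, 8653, was 91.8% of the main count. That number includes genes not called in the main fit, so it does not measure how many calls were kept. Preparation differences that arise library by library were not decided by rank correlation, since pairs of the same group reached an absolute rho of 0.296 with GC content against a smallest value of 0.355 between groups, but a rho does not measure size. The difference in median log2 ratio between the fifth of genes with the highest value and the fifth with the lowest reached 0.203 for GC content and 0.174 for exon length within groups, against at least 0.545 and 0.362 between groups, which argues against them as the whole source of the trend with GC content. For exon length they stay open, since the largest absolute rho within a group, 0.330, exceeded the smallest between groups, 0.245. A preparation difference shared by all libraries of a group stays open, as does a response of the cells that favours short, GC-rich transcripts, since the design does not separate them. Fold changes also fell with gene span, introns included, at a Spearman rho of -0.35, or -0.22 given GC content. That trend was not separated from the one with exon length, so it does not decide between them.

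Some RNAs that mostly lack a poly(A) tail were higher in DHA. Beside the histones, the U1 small nuclear RNA entry, kept as 1 row for its shared name, rose by 4.94 ± 0.22. It went from 0.332 ± 0.0420 to 9.71 ± 0.877 CPM. SNORD3A and RMRP rose by 4.34 ± 0.43 and 5.09 ± 0.76. RMRP was at 4.23 without the DHA library of replicate 2 and at 4.29 with the offset. Less stringent poly(A) selection in the DHA libraries would raise all such classes, but the 25 tested snoRNA, Y RNA, SRP RNA and 7SK entries had a median of -0.034 (quartiles of -0.96 and 1.09), which lies below the histone median of 2.50 by more than that spread, with 8 higher and 7 lower. Their summed level was 45.3 CPM in control and 47.5 CPM in DHA. The 7 tested entries typed as small nuclear RNA, U1 among them, had a median of 3.90, with 4 higher and 2 lower. These values argue only against a rise of all such classes. Less stringent poly(A) selection that raised some of them stays open, as does a response of these RNAs to DHA, which was not tested.

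More genes were detected in DHA at lower depth. Genes with a mean under 1 CPM, olfactory receptors left out, summed to 2609 ± 174 CPM in control and 3558 ± 232 CPM in DHA (SD, n = 3). Genomic DNA in the DHA libraries could raise silent genes, and olfactory receptor genes were taken as such in advance; their summed CPM was 0.857 times that of control. That bound was wrong, because the sum was led by a gene that is expressed here, OR51B4, at 34.6 ± 7.49 CPM in control and 18.9 ± 0.969 CPM in DHA. The 476 olfactory receptor genes under 1 CPM rose 1.80-fold, from 9.25 ± 1.31 to 16.7 ± 2.44 CPM, higher in each DHA library than in each control, so that genomic DNA and a broad rise of weakly expressed genes under DHA cannot be told apart with these tables.

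The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 9431 genes, 2480 at 2-fold and 17 lists in edgeR and camera, in 1 of the 10 splits each; the highest of the other splits gave 0 genes, 0 at 2-fold and 14 lists. At an unadjusted p under 0.05 the other splits gave 37 to 221 genes, against 10052. List calls with a preset correlation were made also in the other splits. Each of those splits holds libraries of both groups on each side, so the difference between the groups adds to the spread within a side. Few gene calls were thus fixed in advance there, and the gene counts of these splits do not measure chance.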
